A study of Caenorhabditis elegans with 4 samples.

How the data were processed

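Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an affinity-purified rabbit polyclonal antibody against LIN-53 on L3-stage larvae of the wild-type Caenorhabditis elegans strain N2 grown at 20 °C. Per the labels' protocols, larvae were frozen, ground and fixed in 1% formaldehyde for 10 min, and chromatin was sheared in 14 sonication pulses of 30 s. The series holds 4 libraries, which are 2 ChIP libraries and 2 input DNA libraries. The labels number them as replicates and do not say whether they came from separate cultures, so agreement between replicates may be technical as well as biological.

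The files analysed are 3 lists of genomic intervals. Each ChIP replicate has a peak list of its own, and a further list covers the whole series and names its entries as consistent sites. Per the file headers, coordinates refer to WormBase build WS220, and the source column of each list names MACS (a peak caller that compares local read pile-up with a background model). Reads were aligned with BWA, per the submitters' processing notes. The versions and settings of both programs, the use of the input libraries as controls, and the way the series list was built are not given in the sources used here. The deposited score of each peak in the replicate lists is at least 2 and its scale is not named. The deposited score of a site in the series list runs from -1.98 to 1.99, so it is on another scale. Scores of the series list and of the replicate lists were therefore never compared in size. Score ratios between the replicate lists, and which replicate scored higher, take both replicate lists to be on 1 scale, which the headers do not state. The series score is not known to measure strength, so the sites at or above its median may not be stronger. No read counts or depths accompany the intervals, so the depth behind each peak is unknown, and intervals given for shares cover counting of peaks only.

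Peaks were counted as partners when they shared at least 1 bp. The share of peaks with a partner was compared with 10000 circular shifts of the other list within each chromosome (one-sided permutation test, smallest possible p 0.0001). Score agreement was calculated across pairs in which each peak overlapped no other peak of the opposite list, with 100000 permutations (smallest possible p 1e-05). Peaks are not independent replicates. Medians were compared by two-sided permutation tests with 100000 resamples. Overlapping peaks of both replicate lists were joined, and regions to which both lists contributed are called regions in both lists. Numbers of peaks per chromosome were compared with the share of total length by two-sided exact binomial tests with Clopper-Pearson 95% intervals and Benjamini-Hochberg adjustment over the 6 chromosomes. The binomial tests treat peaks as independent. Because the headers state no chromosome lengths, the furthest peak end in the 3 lists stood for the length. The middle section of the autosomes, 33.3% of the length of each, was tested against the outer sections in the same way. The position of series sites inside replicate peaks was compared, for sites narrower than their pair, with 1000 uniform placements of each of 2 kinds, over all positions touching both peaks and over all positions inside the outer edges of the pair. Sites were placed independently of each other, also where several lay in the same pair. The share of sites covering the centre was compared between quartiles of the score ratio by permuting the sites.

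Comparisons fixed before the data were examined included tests of peaks near annotated gene starts, of genomic classes, of 23 gene lists and of sequence motifs at peak centres. They were not run, because the gene table at hand refers to the assembly WBcel235, positions were not converted between builds, and no genome sequence was used here. The rule for named items was to take the 12 highest-ranked sites of the series list with their genes and then members of each gene list. As 48 series sites tie at the highest score and genes could not be placed, the regions named are the 12 with the best mean score rank over both replicate lists, a choice made after the data were seen. Other regions named were also chosen after their values were seen. Numbers of protein-coding genes per chromosome were taken from the WBcel235 table as counts, without coordinates.

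Alternatives covered the overlap rule, the entries of each list at or above its median score, equal list lengths, each replicate list in place of the series list, merging of peaks within 500 bp, and expectation by gene number. The overlap and density calculations were tested on simulated data. In 1945 simulated peaks with 60% planted overlap, 60.3% had a partner, against 0.73% for shifted lists. In 706 simulated sites with a planted X density ratio of 0.3, the mean estimate was 0.304. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.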

Results

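LIN-53 is the worm homolog of the retinoblastoma-binding RbAp proteins, a histone-binding subunit shared by several chromatin complexes, among them the DRM (DREAM-like) repressor complex and the NuRD remodelling complex. To map where LIN-53 sits on chromatin in L3 larvae, peaks had been called in 2 ChIP replicates. Replicate 1 gave 1948 peaks that covered 300.04 kb, and replicate 2 gave 2055 peaks that covered 289 kb. With peaks within 500 bp merged, the counts were 1724 in replicate 1 and 1522 in replicate 2, so their order turned round. Each list took up 0.299% and 0.289% of the analysed genome length, respectively. Peaks were narrow. The median width was 136 bp in replicate 1 (interquartile range 86 to 197 bp) and 103 bp in replicate 2 (56 to 203 bp). The widest peak of both lists lay at the same place on chromosome V. It spanned 724105 to 727827 (3723 bp, score 36.5) in replicate 1 and 724241 to 727028 (2788 bp, score 18.3) in replicate 2. The series-wide list held 706 sites with a median width of 79 bp (64 to 114 bp), and these covered 69.1 kb. All positions refer to WS220, and the genes at these positions were not analysed here.

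The first question was which regions scored highest in both replicates. The 12 regions with the best mean score rank lay on chromosomes II (4 regions), III (4 regions), V (2 regions), I (1 region) and IV (1 region), and 0 lay on X. The highest-ranked region was on chromosome V, from 18533382 to 18533954, with a score of 208.73 in replicate 1 and 223.91 in replicate 2. The next on this chromosome spanned 10897212 to 10897588 and scored 202 and 195 in replicates 1 and 2. On chromosome III, the region from 7854344 to 7854766 scored 218 and 158, the region from 7277209 to 7277543 scored 220 and 140, the region from 3867384 to 3867710 scored 161 and 203, and the region from 1950191 to 1950613 scored 159 and 104. On chromosome II, the region from 650386 to 650847 scored 183 and 213, the region from 11534868 to 11535062 scored 166 and 110, the region from 15010374 to 15010729 scored 186 and 98.6, and the region from 10563313 to 10563841 scored 166 and 103. The region on chromosome IV, from 4390480 to 4390860, scored 194 and 143. The region on chromosome I, from 9163350 to 9163669, scored 191 and 99.3. Taken over both lists, the peaks of these regions spanned 195 to 573 bp. The series list had a site in 9 of the 12 regions. It had none in the regions at 3867384 on chromosome III, 9163350 on chromosome I and 11534868 on chromosome II.

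**Figure D1:**
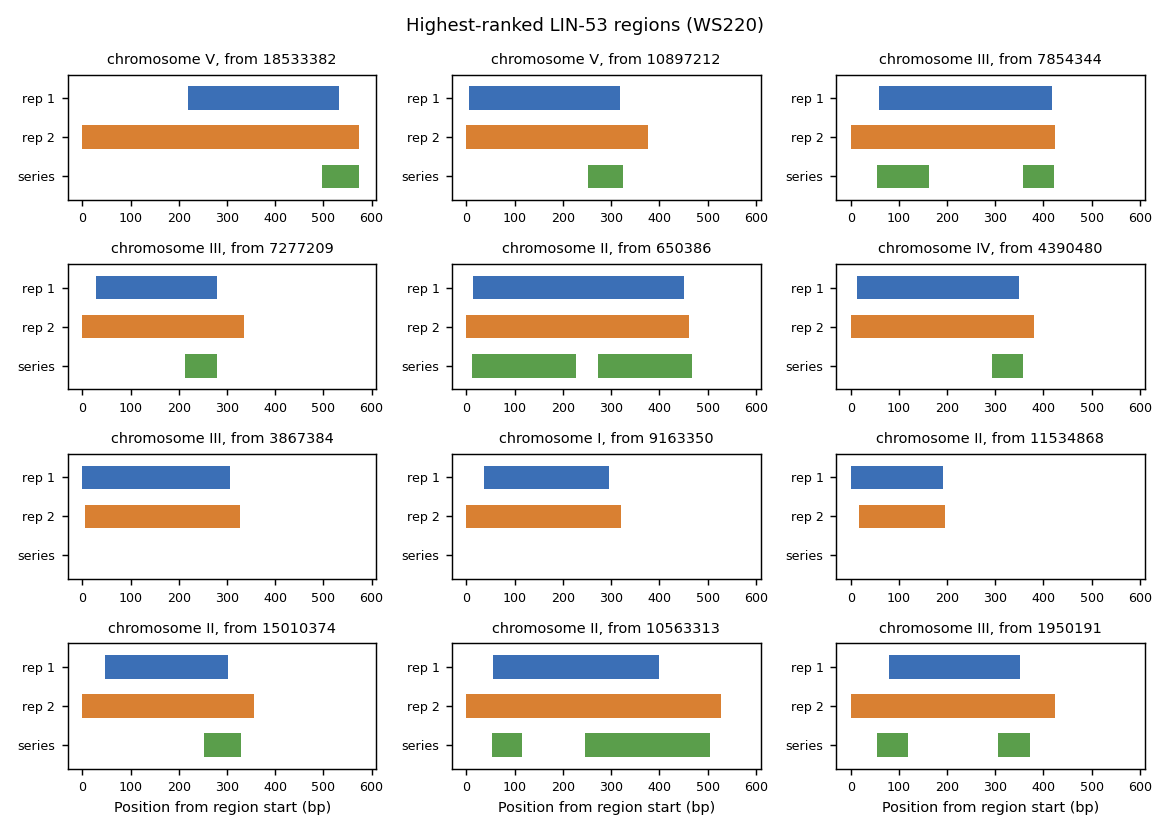
Map of the 12 highest-ranked regions, with the position in bp from the start of each region on the x axis and the peaks of replicate 1 (blue), the peaks of replicate 2 (orange) and the sites of the series list (green) as bars drawn to scale. The replicate peaks overlap in each region, whereas 3 regions have no series site and the sites in 8 of the other 9 regions do not cover the region's centre.

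To find how far the replicates located the same regions, the lists were overlapped. In replicate 1, 1258 of 1948 peaks had a partner in replicate 2, which is 64.6% (95% exact interval 62.4 to 66.7%). In replicate 2, 1318 of 2055 peaks had a partner, which is 64.1% (62.0 to 66.2%). Shifted lists gave 0.658% and 0.645% on average, so both shares lay above all 10000 shifts (permutation p = 0.0001 for each, the smallest these shifts can give). Joining the overlapping peaks gave 1235 regions in both lists, with a median width of 206 bp. The bases in common amounted to 188 kb, or 46.9% of the 401 kb covered by either list. Requiring that partners share at least 50% of both peaks lowered the shares to 49.1% and 46.6%.

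Peaks found in both replicates had higher scores than peaks found in one list. In replicate 1 the median score was 25.07 for peaks with a partner and 6.38 for the 690 peaks without. In replicate 2 it was 11.2 for peaks with a partner and 5.61 for the 737 without. The median score rank differed by 43.8 percentile points in replicate 1 and by 32.5 in replicate 2 (permutation p = 1e-05 for each, the smallest possible). The top quartile of replicate 1, with scores of at least 33.5, had a partner in 486 of 487 cases, against 122 of 487 in the bottom quartile. The exception lay on chromosome IV from 3213517 to 3213681, with a score of 33.53. In replicate 2, 469 of 509 peaks of the top quartile had a partner, or 92.1% (89.5 to 94.3%), against 39.1% (34.9 to 43.5%) in the bottom quartile. The strongest replicate 2 peak with no partner was on chromosome V, from 12510211 to 12510379, with a score of 49.5. Median widths were 174.5 bp with and 82 bp without a partner in replicate 1, and 171 bp and 58 bp in replicate 2.

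**Figure D2:**
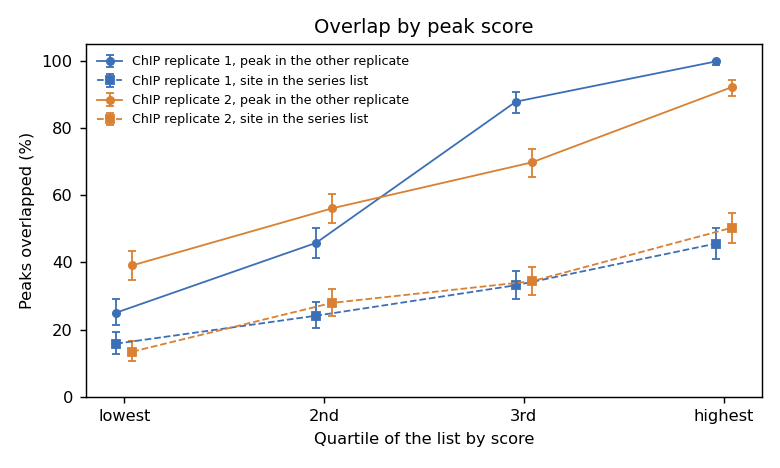
Share of peaks in each quartile of the 2 replicate lists by score (x axis) that overlap a peak of the other replicate (solid lines, circles) or a site of the series list (dashed lines, squares), in percent with 95% exact binomial intervals as bars. Overlap with the other replicate rises to 99.8% and 92.1% in the top quartile, whereas overlap with the series list reaches 45.6% and 50.3%.

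Regions that ranked high in one replicate also ranked high in the other. Across 1149 pairs with a single partner on each side, Spearman's rho was 0.780 and Pearson's r was 0.775 (permutation p = 1e-05 for both). These correlations run across regions, which are not independent replicates. Replicate 1 had the higher score in 974 pairs (84.8%), with a median score ratio of 2.05 (interquartile range 1.33 to 2.96), if both lists use the same score scale. With the pairs above the median score left out, an alternative added after the data were seen, rho was 0.221 over 574 pairs (permutation p = 1e-05). These pairs were chosen by the geometric mean of the same 2 scores, which can by itself lower rho. The value therefore does not measure how far agreement falls among weaker peaks.

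**Figure D3:**
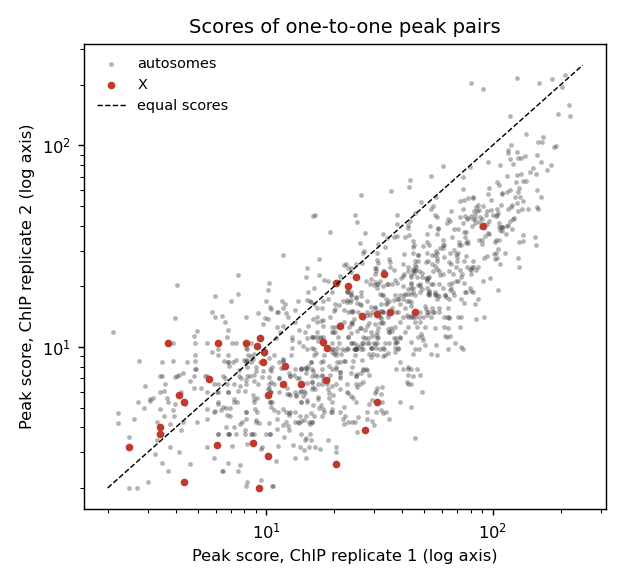
Peak score in replicate 2 against peak score in replicate 1, both on log axes, for the 1149 pairs with a single partner on each side. Each point is a pair (grey for autosomes, red for X) and the dashed line marks equal scores, with 84.8% of pairs having the higher score in replicate 1.

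The series list was then set against the replicate lists. Of its 706 sites, 614 touched peaks of both replicates (87.0%, 95% exact interval 84.3 to 89.4%), 78 touched only replicate 2, 7 touched only replicate 1 and 7 touched neither. Conversely, the series list reached 558 of the 1235 regions in both lists (45.2%) and left out 677. Sites were present in 45.6% of the top quartile of replicate 1 peaks (41.1 to 50.1%) and in 50.3% of the top quartile of replicate 2 peaks (45.9 to 54.7%). The sites were mostly not the common part of the replicate peaks. Both ends lay within 5 bp of that common part in 41 of 591 sites that touched a single peak of each replicate (6.94%). Only 169 sites (23.9%) shared at least 50% of both widths with peaks of both replicates. A site narrower than 50% of a peak cannot meet this rule wherever it lies. The median width was 79 bp for sites, against 174.5 and 171 bp for peaks with a partner in replicates 1 and 2. The low share therefore does not show that sites were displaced.

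Where the replicate peaks were strong, the series sites lay away from their centre. In the top tertile of pairs by geometric mean score, 23 of the 196 sites that were narrower than their pair (11.7%, 7.59 to 17.1%) covered its centre. Uniform placement touching both peaks gave 25.23% on average, and uniform placement inside the pair gave 39.8% (permutation p = 0.001 against each, the smallest possible). Sites of the same pair were placed independently, although separate sites cannot both cover its centre. In the bottom tertile, 133 of 188 sites (70.7%) covered the centre, which is above the 48.4% of the first kind of placement and below the 82.6% of the second. In the middle tertile the share was 37.6%, against 33.7% and 56.8%. Over all 581 sites it was 39.6%, against 35.7% and 59.4%. The share thus fell below the first kind of placement only in the top tertile. Of the 12 highest-ranked regions, 1 had its centre covered (the region from 10563313 to 10563841 on chromosome II), and in 3 regions 2 sites lay on either side of an uncovered centre. On chromosome III, for example, sites at 7854398 to 7854505 and 7854702 to 7854765 flanked the middle of the region from 7854344 to 7854766. In the region from 650386 to 650847 on chromosome II, sites at 650397 to 650613 and 650659 to 650853 left only a short gap at the centre.

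**Figure D4:**
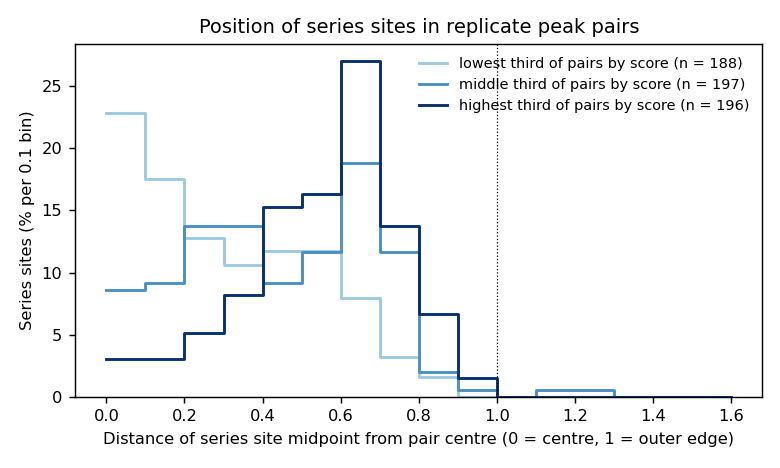
Distribution of the distance between the midpoint of a series site and the centre of the replicate peak pair it touches (x axis, 0 at the centre and 1 at the outer edge, dotted line) as the percentage of sites per bin, for tertiles of the pairs by geometric mean score. In the top tertile the median distance is 0.595, against 0.263 in the bottom tertile.

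LIN-53 peaks were unevenly spread over the chromosomes, with few on X. The series list had 23 sites on X, where 125 were expected from its length, and a density of 1.30 sites per Mb. The density on X relative to the autosomes was 0.157 (95% exact interval 0.0987 to 0.237, adjusted exact binomial p = 1.18e-31). The ratio was 0.247 (0.199 to 0.302) in replicate 1 with 98 peaks on X, and 0.380 (0.320 to 0.448) in replicate 2 with 155 peaks on X. It was 0.164 (0.117 to 0.223) for the 42 X-linked regions in both lists. Thus the deficit was present in each list, and its size differed by over 1.5 times between the series list and either replicate. The strongest X-linked peaks of replicate 1 were at 16930721 to 16932016 (score 101.2, 1296 bp wide) and at 59186 to 59417 (score 90.4). The strongest of replicate 2 lay at 59206 to 59419 (score 39.6), 104788 to 105045 (23.1) and 2089618 to 2089834 (22.2). The 1296 bp peak of replicate 1 also had a partner in replicate 2, but that partner was not among these.

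X-linked peaks scored lower than autosomal peaks and less often had a partner in the other list. Their median score was 7.55 against 14.3 for autosomal peaks in replicate 1 (permutation p = 0.0105), and 5.62 against 8.70 in replicate 2 (permutation p = 0.00015). In replicate 1, 42.9% of X-linked and 65.7% of autosomal peaks had a partner (Fisher's exact p = 7.04e-06). In replicate 2, 32.3% and 66.7% had one (Fisher's exact p = 5.24e-17). X carried 0.821% of the top quartile of replicate 1 peaks and 1.96% of that of replicate 2.

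Among the autosomes, III and I were the most densely occupied and V the least. Each ratio below sets a chromosome against all others, X included, so the low density on X raises the ratio of each autosome. In the series list, III had 11.4 sites per Mb (density ratio to the other chromosomes 1.79, interval 1.49 to 2.15, adjusted exact binomial p = 2.89e-09) and I had 10.4 (ratio 1.604, 1.33 to 1.92, adjusted p = 1.30e-06). Chromosome V had 5.26 sites per Mb (ratio 0.699, 0.565 to 0.859, adjusted exact binomial p = 0.000634). Among series sites at or above the median score its ratio was not past the threshold (0.778, unadjusted exact binomial p = 0.0790). As X was low there too (ratio 0.175) and raised this value, V lay further below the other autosomes than 0.778 shows. That contrast was not tested on its own. The score of the series list is not known to measure strength, so this cut may not select stronger sites. Chromosome II had a ratio of 1.28 in the series list (1.05 to 1.55, adjusted exact binomial p = 0.0165). It was not past the threshold in replicate 2 (ratio 1.09, adjusted exact binomial p = 0.149). Nor was it when expected numbers followed protein-coding genes (ratio 1.10, unadjusted exact binomial p = 0.319). At 8.64 sites per Mb, II lay between I and IV (7.33) in the series list, so an excess over the other autosomes was not shown. Chromosome IV had a ratio of 1.05 in the series list (adjusted exact binomial p = 0.620) and 1.17 in replicate 2 (adjusted exact binomial p = 0.00627). In replicate 2 it had 23.3 peaks per Mb, below I (29.8) and III (27.3) and above II (22.1) and V (15.8). The replicate 2 ratio thus does not show an excess of IV over the other autosomes.

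**Figure D5:**
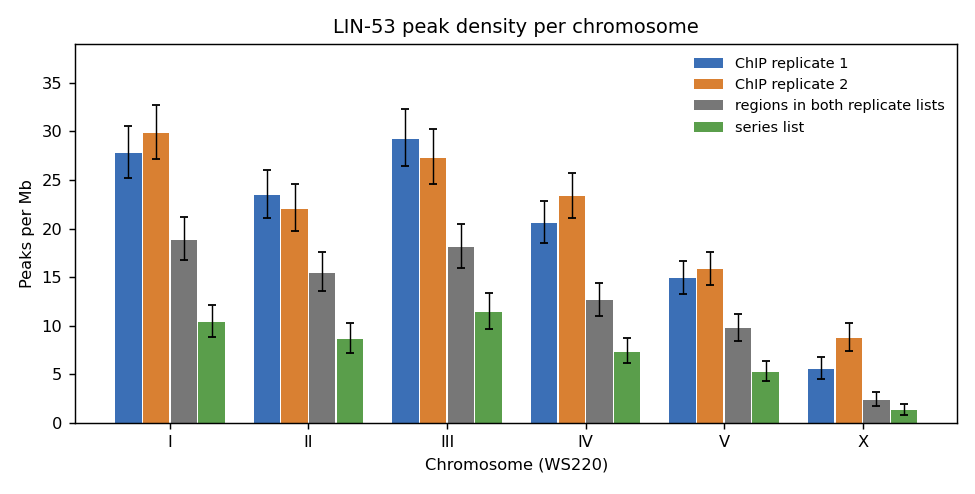
Peaks per Mb on each chromosome for the 2 replicate lists, the regions in both lists and the series list, with exact Poisson 95% intervals as error bars. X is lowest in each list, with 5.53 and 8.75 peaks per Mb in replicates 1 and 2 and 1.30 sites per Mb in the series list.

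Along the autosomes, the middle section, 33.3% of the length of each chromosome, held 243 of 683 series sites (35.6%, 32.0 to 39.3%), which was not past the threshold against the 33.3% expected (exact binomial p = 0.223). This depended on the set of sites used. The share was 41.7% (36.5 to 47.1%) for series sites at or above the median score (exact binomial p = 0.00111) and 37.3% (33.4 to 41.4%) after merging sites within 500 bp (exact binomial p = 0.0466). The first of these sets may differ in the balance of the replicates rather than in strength. The share was 38.9% (36.6 to 41.1%) in replicate 1 (exact binomial p = 6.15e-07) and 35.9% (33.8 to 38.2%) in replicate 2 (exact binomial p = 0.0160). Of the regions in both lists, 37.4% lay in the centre (34.6 to 40.2%, exact binomial p = 0.00319). Chromosome V had the highest share of these, with 91 of 204 regions in its middle section (44.6%, adjusted exact binomial p = 0.00485). The chromosomes past the threshold differed between replicates. They were V (42.4%, adjusted exact binomial p = 0.00544) and I (39.5%, adjusted p = 0.0282) in replicate 1 but only IV (41.5%, adjusted p = 0.00368) in replicate 2, where V had 37.2% (adjusted p = 0.290).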

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

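The use of each replicate list in place of the series list, the overlap rules, the score thresholds and the leave-one-replicate-out settings were chosen before the data were examined. Merging of peaks within 500 bp, regions in both lists, expectation by gene number and the alternatives for score agreement and for scores of peaks with a partner were chosen after seeing the data. Of 57 alternative values for 16 results, 46 kept their direction and side of the threshold or stayed within the allowed range. The share of series sites in both replicate lists moved from 87.0% to 23.9% under 50% reciprocal overlap, a rule that sites narrower than 50% of a peak cannot meet. The middle section of the autosomes went past the threshold in each alternative tried. It held 35.9% to 38.9% when either replicate was left out and the list of the other one was used, 41.7% in the series sites at or above the median score, 37.4% of the regions in both lists and 37.3% after merging. The cause was not tested for either result, and the series score may not measure strength. Chromosome IV, not past the threshold in the series list, turned from a ratio of 1.05 to 0.954 in the sites at or above the median score. It rose to 1.17 without replicate 1. Chromosome II lost its call without replicate 1 (1.09) and by gene number (1.10), and chromosome V in the sites at or above the median score (0.778). These ratios count X among the other chromosomes, and its low density raises them. They do not set IV, II or V against the other autosomes alone. The X ratio kept its call throughout, from 0.157 to 0.380. Leaving out a replicate gives no value for the overlap and score comparisons, which need both lists. No paired analysis was possible because the input libraries have no peak list among the files used here, so no value per replicate exists for both groups. The planned settings for gene starts, genomic classes, gene lists and motifs were not run. Read depth is unknown, so a peak missing from one list cannot be read as absence of binding.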

Other observations

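Of the tests in this part, those of closely spaced autosomal peaks and of pieces of regions called in both lists were set before their result was seen, and the others only afterwards. Some LIN-53 peaks lay closer together than random placement gave, in a share that differed between lists. In replicate 1, 224 gaps between neighbouring peaks were at most 500 bp (11.5% of peaks), against 29.6 on average when peaks were placed at random within the same left, middle or right section of their chromosome. The highest of 1000 placements gave 47. In replicate 2 there were 533 such gaps (25.9% of peaks), against 30.8 on average. Of the regions in both lists, 78 gaps were as short (6.32% of regions), against 13.6 on average (permutation p = 0.001 for each, the smallest possible). The densest 100 kb window held 9 regions in both lists, on chromosome II from 13800001 to 13900000. The highest count in a random placement had a median of 7 and reached 11 (permutation p = 0.045), so this window stood only slightly above chance.

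Series sites lay beside the centre of strong replicate peaks, since 11.7% of sites in the top tertile covered the centre. Each of 1000 placements of either kind gave more (lowest 15.8%), which argues against chance placement of each site on its own. The placements let all sites of a pair cover its centre, which separate sites cannot do. Chance placement that keeps the sites of a pair apart was not tested. An offset between files is argued against as well, since 44.9% of these sites lay to the left of the centre (95% exact interval 37.8 to 52.1%), where an offset would put them on one side. A candidate explanation, that the series list keeps only stretches where the 2 replicate signals differ by less than a set amount, was neither shown nor excluded, since by rising quartile of the score ratio (replicate 1 over replicate 2) the centre was covered by 20.4% (95% exact interval 10.2 to 34.3%), 10.2%, 12.2% and 4.08% of sites (permutation p = 0.0988 for a difference), against 22.6% to 27.5% for uniform placement touching both peaks. In top-tertile pairs with scores within 1.5 times of each other, 18.75% of sites covered the centre, against 26.5% for that placement (permutation p = 0.139). In the other pairs it was 9.46% against 24.6% (permutation p = 0.001). The 2 groups were not compared directly. Single regions with similar replicate scores but uncovered centres go the other way, as at 18533382 and 10897212 on chromosome V. So does the region at 650386 on chromosome II, though only a short gap at its centre was uncovered. The lack of a site in the region at 3867384 on chromosome III, which scored higher in replicate 2, goes the same way. These regions were picked after their values were seen and decide nothing. The series score did go with the difference between replicates. In the top tertile, sites with a score below 0 lay in pairs that scored higher in replicate 2 in 8 of 15 cases. For the rest of the tertile, here with 1 site not narrower than its pair, it was 10 of 182 (odds ratio 18.96, 95% interval 4.95 to 76.5, Fisher's exact p = 4.11e-06). Over all 591 sites it was 29 of 46 against 107 of 545 (odds ratio 6.95, 3.55 to 14.0, Fisher's exact p = 1.33e-09). Between site score and log2 score ratio, Pearson's r was 0.37 (permutation p = 1e-05) and Spearman's rho 0.09 (permutation p = 0.236) in the top tertile. Over all sites, Pearson's r was 0.343 (permutation p = 1e-05) and Spearman's rho 0.154 (permutation p = 0.00017). Sites of the same pair share its score ratio, yet these tests and that between quartiles of the ratio treated them as independent. The score does not show how the centres were lost, and no biological explanation was tested, as the design gives no group for it.

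A lower number of genes does not account for the low number of peaks on X, since the ratio was still 0.213 (95% interval 0.134 to 0.322) when expected numbers followed the protein-coding genes per chromosome, of which X has 2730 (13.7%). Repeated counting of close autosomal peaks does not either, since merging peaks within 500 bp gave 0.170 (0.104 to 0.262). Lower read coverage of X stays open. X made up 1.96% of the top quartile of replicate 2 peaks and 12.6% of the bottom quartile, which both lower coverage and fewer strong binding sites on X would give, and no coverage values were used here. Whether X-linked genes differ in LIN-53 binding because of their expression was not tested.

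In all, 35.4% of replicate 1 peaks and 35.9% of replicate 2 peaks had no partner in the other list. Scores near the calling threshold are consistent with part of this, since 99.8% of the top quartile of replicate 1 peaks had a partner against 25.05% of the bottom quartile, and 92.1% against 39.1% in replicate 2. Of the peaks without a partner, 60 of 690 in replicate 1 (8.70%) but 193 of 737 in replicate 2 (26.2%) were in the upper 2 quartiles of their list, which leaves these open. Pieces of regions that both lists call could account for a smaller part, since 26.6% of replicate 2 peaks without a partner (95% exact interval 23.4 to 29.9%) lay within 500 bp of a replicate 1 peak, as did 18.99% in the opposite direction, against 2.32% and 2.24% for shifted lists. Peaks under 60 bp made up 52.6% of replicate 2 peaks without a partner and 14.1% of those with one.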
